A study of Homo sapiens with 6 samples.

How the data were processed

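The series holds 6 RNA-seq libraries of A375 human melanoma cells, 3 from monoculture and 3 from coculture with 3T3-L1 mouse adipocytes, after 7 days and sorting. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was isolated with a commercial kit and made into Illumina libraries. Per the submitters' processing notes, STAR 2.5.0a, DESeq2 and the genome builds hg19 and mm10 were used, with no role or order stated. The labels also name HTSeq. The annotation, the strand setting, the handling of mouse reads and the version of DESeq2 were not given in the sources used here.

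The deposited table gives 1 signal value per gene and library, for 45021 rows named by gene symbol. The values are not whole, but in each library they are whole multiples of 1 step, as gene read counts divided by a size factor per library would be. Dividing by the step gave whole reads to within 0.01 of a read for 100% of the values in each library, with factors between 0.975 and 1.02. An automated check of units accepted this recovery for 3 of the 6 columns, since in the other 3 (monoculture replicates 1 and 2 and coculture replicate 1) the factor lies too near 1 for it to tell the step from rounding. The recovery in those 3 columns rests on the test of the values described here, and the count tests used all 6 columns. Recovered depth was 15675078 to 16527575 reads per library, so that 3 reads, the limit that a count of 0 allows, correspond to 0.181 to 0.191 CPM.

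The design fixed before the data were examined assumed raw counts and edgeR's quasi-likelihood test. Because the deposited values are normalised, the main test was instead limma 3.58.1 (R 4.3.3) with an intensity trend on log2(value + 1), with no further scaling. Genes needed a value of at least 10 in at least 3 libraries, and calls were made at a Benjamini-Hochberg adjusted p under 0.05. No block was fitted. Of the 14959 genes tested, 13212 symbols were found in the table of gene names and 13538 in GENCODE v29. That annotation is on another build than hg19, so no coordinates are given and it was used only for gene type, transcript length and GC content. In 28 rows a date stood in place of the symbol. Of these rows 22 were tested and counted, and none was named. No unmapped column was used.

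A total of 22 gene lists were fixed before the data were examined: fatty acid uptake and activation, fatty acid synthesis and desaturation, cholesterol synthesis, fatty acid oxidation, PPAR targets, lipid droplets and triglyceride turnover, melanocyte differentiation, the undifferentiated and invasive melanoma state, DNA replication and S phase, mitosis, hypoxia and glycolysis, oxidative phosphorylation, type I interferon response, inflammatory NF-kB targets, ATF4 and endoplasmic reticulum stress, MAPK pathway output, NRF2 antioxidant response, extracellular matrix and collagens, adipocyte markers, fibroblast and preadipocyte markers, mitochondrially encoded transcripts and cytosolic ribosomal proteins. Lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation beside it, and with fry, adjusted over the 22 lists. Another 6 lists (LXR targets, ribosome biogenesis, YAP targets, MHC class II, immediate early genes, and retinoid metabolism and response) were written after the first results had been seen.

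The naming rule, also fixed before, took the 6 FATP genes, the 6 largest rises and 6 largest falls among called genes with a mean of at least 10 CPM and non-overlapping groups, and for each list the 3 called members with the largest change, or the 2 most expressed members where fewer than 2 were called. It left out clone-based, LOC, LINC, antisense, pseudogene-type, mitochondrial, ribosomal-protein and small RNA names from the largest changes. The pattern for pseudogene-type names was widened after the values had been seen, which removed SFTA1P from the 6 largest rises and put MYC there. MYC was also named by its list. Other genes named for their lists (SOX10, MITF, AXL, MMP1, MMP2, PMVK, HSPA5, CD36, FABP4 and ADIPOQ) were chosen after their values were seen. Some genes that the rule or the lists cover were included in all tests and counts but are not reported here, and the heat map leaves out such genes.

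Replicates were compared with a chi-square test of recovered reads over 11923 genes with a mean of at least 50 reads. Pairs within a group gave 2.53 to 7.26 per degree of freedom and pairs between groups 85.3 to 101, so that every pair differed by more than sampling noise. Shares of mitochondrial reads were compared with an exact permutation test. The procedure was tested on simulated data of the same libraries, with 14734 genes tested. At each fold 50 genes were changed, all with a mean of at least 50 normalised reads. The procedure recovered 70% at 1.25-fold, 88% at 1.5-fold and 100% at 2-fold and 3-fold, with 8 false calls. Far fewer genes were changed than were called in the real data, and no gene of lower expression was changed. These figures therefore do not give the recovery or the false calls of the real comparison. Alternatives were edgeR 4.0.16 with other size factors, DESeq2 1.42.0 and limma-voom on recovered reads, other filters and thresholds, a block on the replicate number and leaving out each library. edgeR with TMM, pseudocounts of 0.5 and 4, and TMM scaling of the values were added after the data were seen.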

Results

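RNA was sequenced from A375 cells, an established human melanoma line that carries a BRAF mutation and here expressed GFP. The cells had been grown either alone (monoculture) or together with adipocytes made from the mouse 3T3-L1 line (coculture), in both cases for 7 days in adipocyte maintenance medium, and were then isolated by fluorescence-activated sorting. Each group held 3 libraries. The libraries held between 15675078 and 16527575 reads counted on genes, so that 1 read corresponded to about the same share of the total in each. The single comparison, coculture against monoculture, asks how melanoma cells change their gene expression next to adipocytes, and the series title points to adipocyte lipids and the fatty acid transport proteins (FATP, encoded by SLC27A1 to SLC27A6). Values below are normalised reads as mean ± SD with n = 3 per group, and fold changes are taken on the log2(value + 1) scale, which understates the change of genes with few reads.

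Cocultured A375 cells had much lower expression of cholesterol synthesis genes than cells grown alone, with 23 of 24 tested genes lower and a median log2 fold change of -1.72. INSIG1, a sterol-regulated brake on this pathway, fell 10.2-fold, from 9716 ± 377 to 953 ± 42.7 normalised reads. Hypoxia and glycolysis genes, genes of fatty acid synthesis and genes of melanocyte differentiation were lower as groups, whereas genes of DNA replication and mitosis were slightly higher. These list calls hold at a preset correlation and were lost with an estimated correlation, with adjusted p = 0.169 for cholesterol synthesis, fatty acid synthesis, melanocyte differentiation and DNA replication, adjusted p = 0.189 for hypoxia and glycolysis and adjusted p = 0.571 for mitosis. Among single genes MYC, a transcription factor that drives growth, rose 7.36-fold, and the cytokine gene IL1B fell 29.9-fold. Of the FATP genes, SLC27A1 and SLC27A3 fell, SLC27A5 and SLC27A6 rose and SLC27A4 did not pass the test. The rise of SLC27A6 rested on few reads and was called in 14 of 16 alternatives.

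Of 14959 genes tested, 9335 (62.4%) changed at a Benjamini-Hochberg adjusted p under 0.05 in limma, 4677 of them higher and 4658 lower in coculture. Many of these changes were small: 1843 genes changed at least 2-fold, and of these 1188 were lower and 655 higher. In 67.2% of the tested genes the 3 coculture values lay wholly above or wholly below the 3 monoculture values, against 10% by chance. The first principal component took 84% of the variance and separated the groups. Among the 6 largest rises of genes that met the naming rule were those of ANKRD1, an ankyrin repeat protein and YAP target (15.6-fold, from 224 ± 23.2 to 3501 ± 446 normalised reads), the chloride channel gene BEST2 (13.1-fold), the secreted proteoglycan gene ESM1 (11.3-fold), CCBE1 (7.40-fold) and MYC. The largest falls were those of the protease inhibitor gene A2M (33.6-fold, from 3255 ± 36.5 to 98.2 ± 27.4 normalised reads), the transcription factor gene NFATC2 (30.4-fold), IL1B, the hyaluronan-binding protein gene CEMIP (19.8-fold), MYOZ2 (17.7-fold) and the secreted glycoprotein gene STC1 (15.8-fold).

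SLC27A1 fell by 0.96 on the log2 scale (SE 0.0646, adjusted p = 2.15e-09), from 1276 ± 54.5 to 658.6 ± 48.6 normalised reads. SLC27A3 fell 2.29-fold, from 170.1 ± 17.4 to 73.6 ± 5.51 (adjusted p = 4.13e-07), and SLC27A5 rose 1.71-fold, from 259.5 ± 17.9 to 444 ± 6.49 (adjusted p = 3.03e-07). SLC27A4 was at 1075 ± 36.1 in monoculture and 1086 ± 44.7 in coculture (log2 fold change 0.01, 95% interval -0.106 to 0.136, adjusted p = 0.836). SLC27A6 rose by 0.98 on the log2 scale (adjusted p = 0.0124), from few reads: 30 over the monoculture libraries and 64 over the coculture libraries. Its call was lost without coculture replicate 2 (log2 fold change 0.73, adjusted p = 0.0876) and in DESeq2 (adjusted p = 0.0556), within a range of 0.00378 to 0.0876 over its alternatives. SLC27A2 had 3 reads over the monoculture and 4 over the coculture libraries and lay below the filter, so that a difference was not detectable at this depth.

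**Figure D1:**
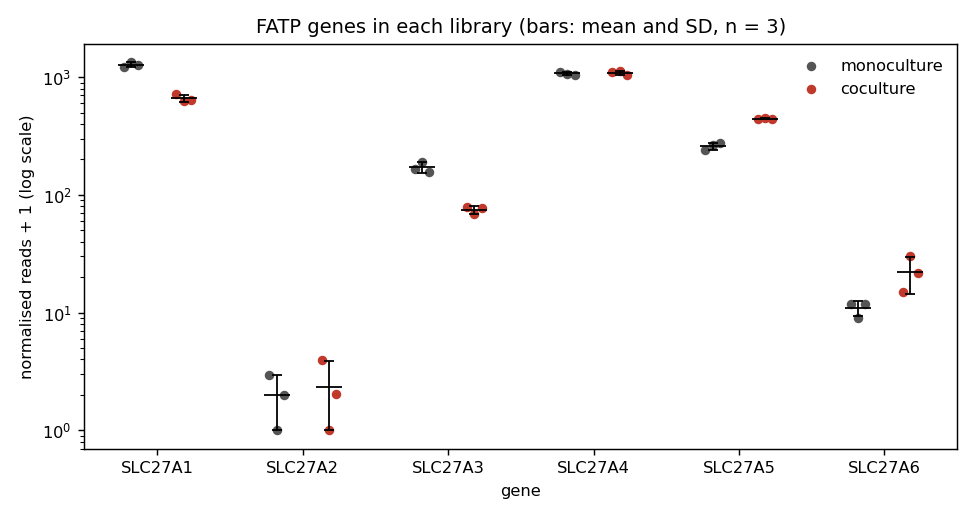
Normalised reads (plus 1, on a log axis) of the 6 FATP genes in each library, with points for libraries and bars for the mean and SD of 3 libraries per group. SLC27A1 and SLC27A3 lie lower in coculture, SLC27A5 and SLC27A6 higher, SLC27A4 overlaps, and SLC27A2 has few reads in either group.

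The wider list of fatty acid uptake and activation genes moved both ways, with 5 of 15 higher and 7 lower (camera adjusted p = 0.374 for the list). The acyl-CoA synthetase genes ACSL3 and ACSL1 fell 3.33-fold and 2.88-fold. LPL, the lipoprotein lipase gene, rose 2.94-fold, from 289.8 ± 15.7 to 853 ± 6.48, and is also a marker of adipocytes. The scavenger receptor gene CD36 was below the filter, with 33 reads over the monoculture and 7 over the coculture libraries.

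Fatty acid synthesis and desaturation genes were lower as a group, with 15 of 20 lower and 4 higher (median log2 fold change -0.68, camera adjusted p = 0.000103, and adjusted p = 0.169 with an estimated correlation). ACSS2, which makes acetyl-CoA from acetate, fell 4.54-fold, and SCD, the main stearoyl-CoA desaturase, fell 3.81-fold. ELOVL2, an elongase of long polyunsaturated fatty acids, rose 3.99-fold from a low level of 6.95 ± 1.07 normalised reads. In the cholesterol synthesis list none of the 24 genes was higher (camera adjusted p = 1.35e-17, and adjusted p = 0.169 with an estimated correlation). HMGCS1, which makes HMG-CoA, fell 7.12-fold, and the sterol carrier gene STARD4 fell 6.41-fold. PMVK was the 1 gene of the list that did not pass the test (log2 fold change 0.10, adjusted p = 0.17).

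Lipid droplet and triglyceride turnover genes were lower as a group, with 9 of 19 lower and none higher (median log2 fold change -0.16, camera adjusted p = 0.0195, and adjusted p = 0.252 with an estimated correlation). The other 10 did not pass, and 4 of the 19 fell at least 2-fold, so that much of the list moved little. The lipase genes PNPLA3 and LIPE fell 5.54-fold and 4.16-fold, and the droplet coat gene PLIN4 fell 2.73-fold. LIPE, PNPLA3 and PLIN4 are also in the list of adipocyte markers. Fatty acid oxidation genes were split, with 5 of 26 higher and 11 lower (camera adjusted p = 0.374), and each of the largest changes was below 1.5-fold: ACAA1 fell 1.48-fold, CPT1A, the gate of mitochondrial import, fell 1.46-fold, and ECHS1 rose 1.45-fold. PPAR targets were split too, with 4 of 15 higher and 8 lower (camera adjusted p = 0.225). ANGPTL4, an inhibitor of lipoprotein lipase, fell 2.24-fold and KLF10 rose 2.18-fold. FABP3 fell 2.20-fold, from 52 reads over the monoculture libraries to 22 over the coculture libraries.

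**Figure D2:**
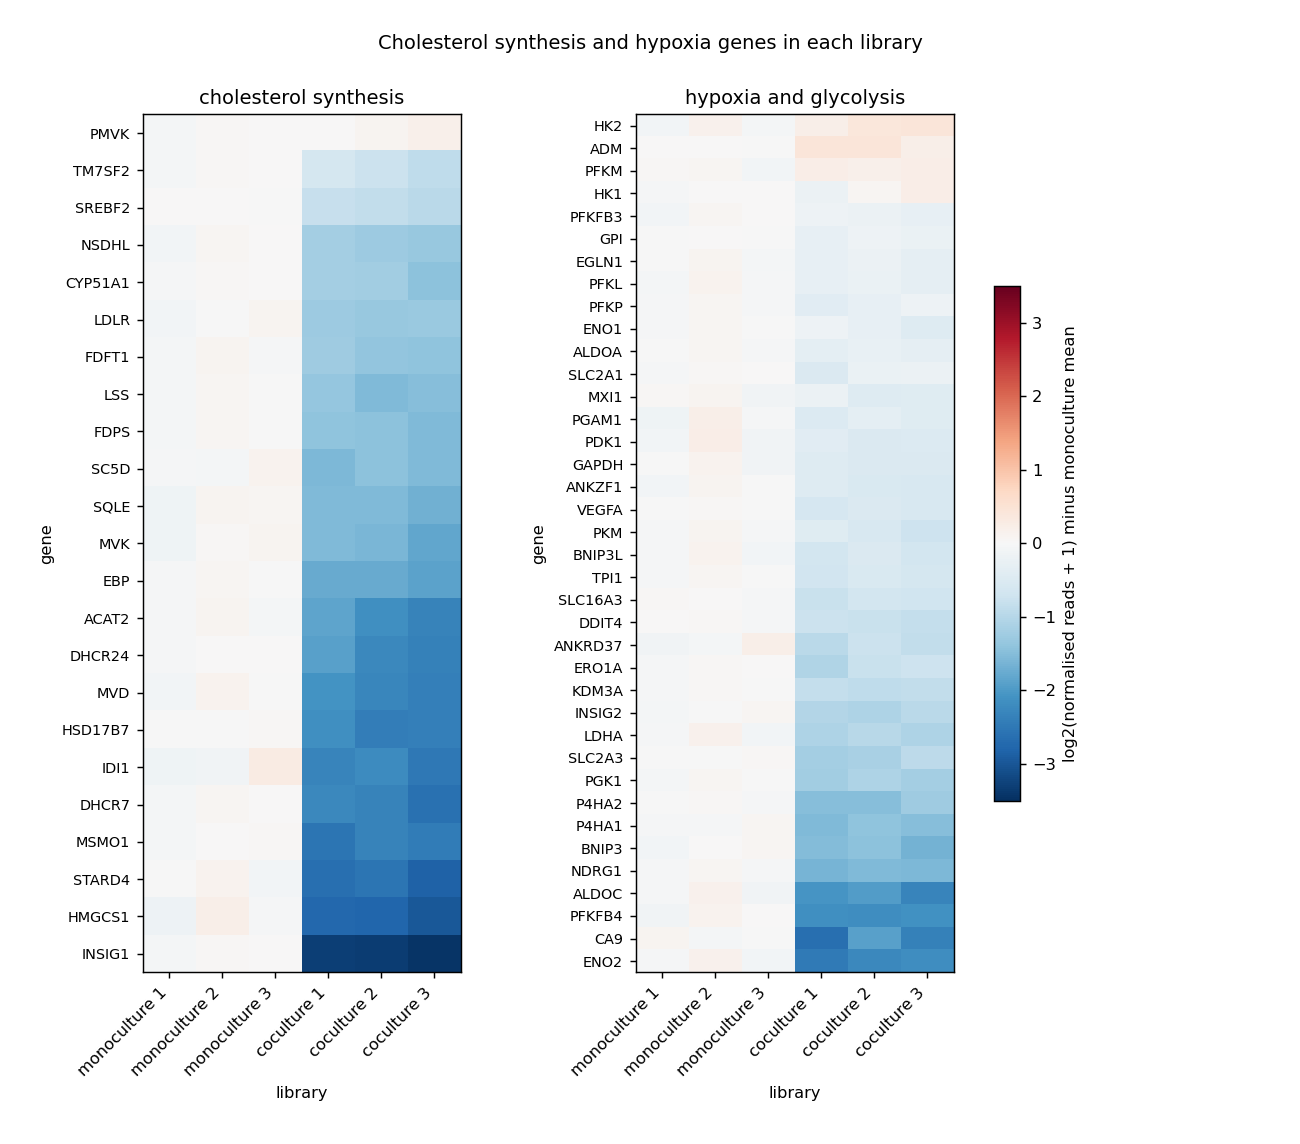
Log2(normalised reads + 1) minus the monoculture mean for each gene (rows) and library (columns) in the cholesterol synthesis and the hypoxia and glycolysis lists, with blue for lower and red for higher values. In the 3 coculture libraries 22 of the 23 cholesterol synthesis genes shown and 34 of the 38 hypoxia and glycolysis genes are lower, led by INSIG1 and ENO2.

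Hypoxia and glycolysis genes were lower in 34 of 38 cases and higher in 3 (median log2 fold change -0.59, camera adjusted p = 3.69e-11, and adjusted p = 0.189 with an estimated correlation). The enolase gene ENO2 fell 4.95-fold, CA9, a carbonic anhydrase induced by low oxygen, fell 4.91-fold, and the glycolytic regulator gene PFKFB4 fell 4.43-fold. All 13 mitochondrially encoded transcripts were lower (median log2 fold change -0.54, camera adjusted p = 0.000143, and adjusted p = 0.352 with an estimated correlation), among them MT-ND6 (1.79-fold), MT-ATP8 (1.65-fold) and MT-CO3 (1.58-fold). Their share of all counted reads was 2.80 ± 0.196% in monoculture and 2.10 ± 0.118% in coculture (SD, n = 3, two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). Nuclear genes of oxidative phosphorylation moved both ways, with 28 of 77 higher and 16 lower (camera adjusted p = 0.223). CYCS, which encodes cytochrome c, rose 1.64-fold, NDUFS6 rose 1.5-fold and COX7A2 fell 1.48-fold.

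Tested melanocyte differentiation genes were lower, with 12 of 18 lower and 1 higher (median log2 fold change -1.23, camera adjusted p = 7.6e-05, and adjusted p = 0.169 with an estimated correlation). The list holds 25 genes. Its members that were not tested, among them pigment genes, had at most 6 reads in any library, so that a loss of these could not be seen. The pigment enzyme gene DCT fell 11.7-fold, from 115 reads over the monoculture libraries to 8 over the coculture libraries. BCL2A1 fell 6.19-fold, from 114 to 16 reads counted in the same way, and the receptor gene ERBB3 fell 4.79-fold. SOX10, a lineage transcription factor, fell 2.86-fold, while MITF, the melanocyte master regulator, was the 1 gene of the list that rose (1.40-fold). In the list for the undifferentiated and invasive melanoma state 17 of 29 genes were higher and 9 lower (median log2 fold change 0.40, camera adjusted p = 0.0763). This list passed in 5 of 19 alternatives, among them camera with the replicate block (adjusted p = 0.0486). The matricellular gene CYR61 (6.65-fold) and the transcription factor gene SOX9 (4.41-fold) rose, and AXL rose 2.20-fold, whereas MMP1 and MMP2, which encode collagen-degrading enzymes, fell 4.37-fold and 3.02-fold.

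DNA replication and S phase genes were higher as a group, with 26 of 47 higher and 6 lower (median log2 fold change 0.24, camera adjusted p = 0.00392, and adjusted p = 0.169 with an estimated correlation). CDCA7 rose 3.45-fold, the exonuclease gene EXO1 2.21-fold and MCM10, a replication initiation factor, 2.18-fold. Of the mitosis genes 24 of 55 were higher and 1 lower (median log2 fold change 0.18, camera adjusted p = 0.00171, and adjusted p = 0.571 with an estimated correlation). The other 30 mitosis genes did not pass, whereas 62.4% of all tested genes changed. Leaving out 1 library gave this list an adjusted p between 0.0001 and 0.0309, the highest without monoculture replicate 1, and fry gave 0.0484. The kinase gene AURKB rose 2.09-fold, UBE2C 1.98-fold and RANGAP1 1.78-fold. Cytosolic ribosomal protein genes were slightly higher, with 34 of 77 higher and 6 lower (median log2 fold change 0.13, camera adjusted p = 0.00841, and adjusted p = 0.248 with an estimated correlation). Without monoculture replicate 2 the adjusted p of this list was 0.0582, within 0.000517 to 0.248 over its alternatives. RPS10 (1.82-fold), RPL39L (1.61-fold) and RPS27L (1.56-fold) rose most. RPS10 had few reads, 85 over the monoculture and 156 over the coculture libraries. Reads of ribosomal protein genes are uncertain because near-identical copies may share them.

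NRF2 antioxidant genes were lower, with 17 of 22 lower and 2 higher, or 18 lower when adjusted over the list alone (median log2 fold change -0.64, camera adjusted p = 1.13e-05, and adjusted p = 0.169 with an estimated correlation). The aldo-keto reductase genes AKR1C2, AKR1C1 and AKR1C3, which are near-identical and may share reads, fell 4.24-fold, 3.63-fold and 3.25-fold. Genes of the ATF4 and endoplasmic reticulum stress list were lower in 21 of 32 cases and higher in 3 (median log2 fold change -0.29, camera adjusted p = 0.000143, and adjusted p = 0.169 with an estimated correlation). VLDLR, a lipoprotein receptor gene, fell 5.12-fold, the cystine transporter gene SLC7A11 2.19-fold and the serine synthesis gene PSAT1 1.98-fold, while the chaperone gene HSPA5 rose 1.42-fold.

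Type I interferon response genes were lower, with 20 of 32 lower and 2 higher (median log2 fold change -0.35, camera adjusted p = 0.000573, and adjusted p = 0.224 with an estimated correlation). The antiviral genes IFIT1 and IFIT2 fell 5.13-fold and 2.92-fold, whereas IFI44L rose 2.66-fold from 12.3 ± 5.24 normalised reads. Inflammatory NF-kB targets went both ways, with 11 of 27 higher and 12 lower (camera adjusted p = 0.669). IL1B fell 29.9-fold. PTGS2, which encodes cyclooxygenase-2, fell 12.7-fold, from 158 reads over the monoculture libraries to 11 over the coculture libraries. The cytokine gene IL6 rose 11.7-fold, from 11 reads over the monoculture libraries to 152 over the coculture libraries. MAPK pathway output was split as well, with 8 of 21 higher and 10 lower (camera adjusted p = 0.508). Besides MYC, the phosphatase gene DUSP5 rose 2.63-fold, and the immediate early gene FOS fell 2.98-fold.

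Extracellular matrix and collagen genes were lower, with 19 of 33 lower and 7 higher (median log2 fold change -0.37, camera adjusted p = 0.00516, and adjusted p = 0.187 with an estimated correlation). LUM, a small proteoglycan gene, fell 8.03-fold, COL8A1 7.65-fold and COL6A3 3.37-fold. Of the fibroblast and preadipocyte markers 4 of 16 were higher and 8 lower (camera adjusted p = 0.0797), with LUM and COL6A3 down and ACTA2, a smooth muscle actin gene with close relatives that may share reads, up 3.24-fold. Of the adipocyte markers 1 of 10 was higher and 4 lower (camera adjusted p = 0.225). The 1 gene that rose was LPL, and the 3 largest falls were those of PNPLA3, LIPE and PLIN4. FABP4, a fatty acid binding protein abundant in adipocytes, had 9 reads over the monoculture and 8 over the coculture libraries, and the adiponectin gene ADIPOQ had 0 in every library, which allows up to 0.191 CPM in coculture (counting error only).

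**Figure D3:**
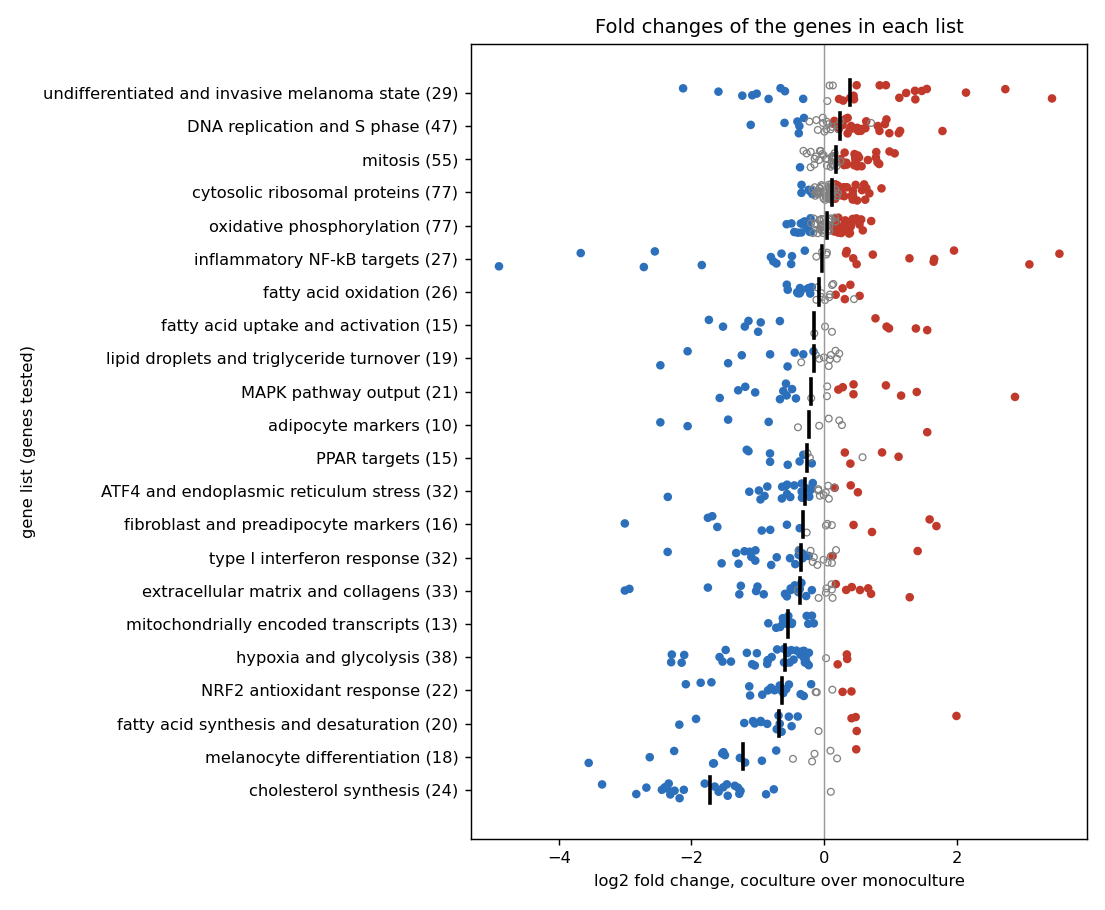
Log2 fold changes (coculture over monoculture, x axis) of the tested genes of the 22 lists, with red and blue points for genes higher and lower at adjusted p under 0.05, open points for the rest and black bars for list medians. Cholesterol synthesis lies lowest, with a median of -1.72, and the undifferentiated and invasive melanoma state highest, with a median of 0.40.

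In camera with a preset correlation 13 of the 22 lists passed, 10 lower and 3 higher. With an estimated correlation 0 of the 22 passed (6 at an unadjusted p under 0.05). By fry, which tests each list on its own, 21 of 22 passed. With so many genes changed, fry can pass a list that leans only slightly, such as oxidative phosphorylation (median log2 fold change 0.04). Its calls therefore do not set a list apart from other genes. The counts within lists were the same when adjusted over the list alone for 21 of the 22 lists. They stand against 62.4% of all tested genes changed, so that many calls within a list do not by themselves set it apart. Nothing states that the replicates came from separate cultures, so that the p-values measure only the spread between these libraries, which may be technical. Genes that may share reads with near-identical copies are uncertain. Genes with an overlapping antisense partner are uncertain too, because the strand setting of the counting was not given in the sources used here.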

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

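The tests with edgeR and TMM, both other pseudocounts and the TMM-scaled values were chosen after the data were seen. The counts of changed genes stayed within 1.5 times of 9335 under each other scaling, filter and test on all libraries, from 7040 with at least 10 CPM in 3 libraries to 9444 without a filter. edgeR with TMM on recovered reads called 9378 genes, of which 9237 were shared with limma and had the same sign, limma-voom called 9369 and DESeq2 8222 (9087 of its rows had no adjusted p). The median log2 fold change of all tested genes stayed between -0.0407 and 0.0322 over these settings. Leaving out 1 library gave 8276 to 9048 changed genes, 4079 to 4470 higher and 4003 to 4578 lower. Counts fell by construction with a threshold of at least 2-fold (1843 changed, 655 higher, 1188 lower) and when tested against a 1.5-fold change (2026 changed, 821 higher, 1205 lower), and an adjusted p under 0.01 left 7711. With the replicate block 9298 genes changed, 4660 higher and 4638 lower. Deviations of libraries with the same number correlated at 0.00406, -0.0215 and 0.0335, and not every library correlated best with its own number. Little variation was thus shared by number, which does not exclude that libraries with the same number came from a shared day or batch.

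With an estimated correlation none of the 13 called lists passed: 0.169 for cholesterol synthesis, fatty acid synthesis, melanocyte differentiation, S phase, ATF4 and NRF2, 0.187 for extracellular matrix, 0.189 for hypoxia, 0.224 for interferon, 0.248 for ribosomal proteins, 0.252 for lipid droplets, 0.352 for mitochondrially encoded transcripts and 0.571 for mitosis. By construction this test allows for genes of a list moving together. The other settings kept these calls, except that ribosomal proteins ranged from 0.000717 to 0.0582 when 1 library was left out, with 0.0582 without monoculture replicate 2. The list for the undifferentiated and invasive melanoma state (0.0763) passed with upper-quartile factors (0.0487), no filter (0.0172), DESeq2 (0.0147) and the replicate block (0.0486), over a range of 9.3e-05 to 0.431. The fibroblast and preadipocyte list (0.0797) passed with at least 10 CPM (0.00488), with DESeq2 (0.00552) and without coculture replicates 1 (0.0324), 2 (0.0291) and 3 (0.049), from 0.0291 to 0.0877 when 1 library was left out and 0.000214 to 0.224 over all. The cause was not tested. fry, which compares a list with no other genes, also passed fatty acid uptake (0.000136), fatty acid oxidation (0.0484), PPAR targets (0.00336), the invasive state (9.3e-05), oxidative phosphorylation (0.0246), NF-kB targets (0.0367), adipocyte markers (0.00468) and fibroblast markers (0.000214).

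Of 1240 values of named genes under the alternatives, 1238 kept their side of the threshold, 2 lost the call (both SLC27A6) and no called gene changed sign (SLC27A4, not called, lay between -0.03 and 0.05). FABP3 stayed just under the threshold in DESeq2 (adjusted p 0.04995, from 0.00242) and fell below the filter without each monoculture replicate, and was not tested there. Among the lists and named genes, the block changed only the call of the invasive state list. The alternative with library sizes over both species was not run, since no separate mouse rows were analysed here. Depth limits low genes such as SLC27A2.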

Other observations

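The lists for MHC class II, immediate early genes and retinoid genes were chosen after values of their leading members had been seen, and no p from them is independent evidence. MHC class II genes, which present antigen, were lower in 12 of 12 tested cases (median log2 fold change -2.41), with CD74 down 7.44-fold, HLA-DRA 9.23-fold and their activator CIITA 3.35-fold. HLA-DRB1 and HLA-DRB5 may share reads and are uncertain. Of 12 immediate early genes 9 were lower and 2 higher: NR4A1 fell 7.08-fold and EGR3 6.05-fold, while JUN rose 2.48-fold. Of 10 genes of retinoid metabolism and response 8 were lower and 2 higher, with DHRS3 down 13.6-fold and the retinol receptor gene STRA6 12.0-fold. Adjusted over the 6 lists of this part, camera gave 5.34e-11, 0.00103 and 0.000516 for these lists, and 0.0534, 0.0746 and 0.0534 with an estimated correlation.

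Tests of mouse RNA and of other splits were written before the data were examined. The patterns tested in the rest of this part, on transcript length, sterol load, MYC and YAP, were chosen after the main results had been seen, before the values that each test measures, and the genes named from their lists were picked after those values were seen. In 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave as many as 9335 changed genes, and the highest of the other splits gave 0. Each other split mixes the groups, so that a large group difference enters its spread and hardly any call could arise. Nor can the share of splits fall below 0.1 with 10 splits. The splits therefore cannot tell whether chance was at work.

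Genes higher in coculture could come in part from mouse adipocyte RNA counted on human genes, although the sort for GFP would remove most adipocytes. The bound written in advance, FABP4, ADIPOQ and CFD all under 1 CPM in coculture, was not met, because CFD reached 7.34 CPM. That bound was badly chosen, since CFD averaged 5.64 CPM in monoculture already. The opposite outcome was not met either: of 7 genes abundant in adipocytes, CFD and LPL were higher in every coculture library, whereas FABP4, ADIPOQ, CIDEC, PLIN1 and SCD were not. SCD averaged 1180 CPM in monoculture and 310 CPM in coculture, so that its own fall would hide a mouse contribution. FABP4, ADIPOQ, CIDEC and PLIN1 stayed under 1 CPM in coculture. Their counts can bound the share of adipocyte RNA only as far as mouse reads of these genes align to the human ones. How well mouse reads align to human genes was not tested, so the comparison cannot decide, and mouse reads on highly conserved genes stay open.

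The fall of cholesterol synthesis genes was weighed against a trend of fold change with transcript length and GC content and against a higher sterol load. The trend took 0.491% of the variance of all log2 fold changes, and the median of the list was -1.72 before and -1.69 after it was removed, which argues against the trend as the whole cause. A higher sterol load may lower these genes through SREBP2, and LXR targets would then be higher. Of 9 LXR targets 4 were higher and 4 lower. Their median log2 fold change was -0.20 and their mean 0.08, and camera pointed down with an unadjusted p = 0.896. ABCA1 and ABCG1 rose 4.70-fold and 3.54-fold, APOE and APOC1 fell 2.55-fold and 3.04-fold. These members go both ways and leave a sterol load open.

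For the hypoxia and glycolysis genes the same correction moved the median log2 fold change from -0.59 to -0.546, which argues against that trend as the whole cause. Differences in oxygen, cell density or nutrients between the cultures may contribute and were not tested.

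The rise of MYC may have gone with a higher MYC output. Of 30 ribosome biogenesis genes, known as MYC targets, 28 were higher and 0 lower in limma (the other 2 did not pass, camera unadjusted p = 1.22e-14 and adjusted p = 7.34e-14), and the call was lost with an estimated correlation (unadjusted p = 0.011, adjusted p = 0.0534), with DKC1 up 2.86-fold and NOP56 up 2.51-fold. Other growth signals raise the same genes and were not tested. A higher YAP output is likewise a hypothesis for the rise of ANKRD1, CYR61 and CTGF. Of 16 further YAP targets 9 were higher and 4 lower (median log2 fold change 0.23, camera unadjusted p = 0.0167 and adjusted p = 0.02), and did not pass with an estimated correlation (unadjusted p = 0.0622, adjusted p = 0.0746), with TGFB2 up 3.14-fold and CRIM1 up 2.80-fold. TGF-beta and serum response factor share several of these targets, so that YAP is 1 of several regulators that remain open.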
